A study of Homo sapiens with 3 samples.

How the data were processed

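Single cells from human omental adipose tissue were measured in 3 libraries, all labelled as mesothelial cells and as prepared with a mesothelial isolation protocol. Per the labels, the libraries were made with the 10x Genomics Single Cell 3' kit (v3) and read with 26 cycles for read 1, 58 for read 2 and 8 for the index, and the authors used Cell Ranger 3.1.0. Values in the deposited matrices are counts: UMI counts per gene and barcode, as whole numbers without normalization. Barcodes with fewer UMIs had already been left out, since the lowest total was 501, 500 and 500 UMIs in libraries 1, 2 and 3. How cells were called cannot be read from this. The labels list the mouse build mm10, but all 33538 feature identifiers are human Ensembl genes; the human build and annotation are not given in the sources used here, and no coordinates were used. Reads were not used here. The libraries were checked for duplication on the summed counts of their mesothelial-like cells, named as described below. Over genes, the Pearson correlation of log2(CPM + 1) was 0.962, 0.930 and 0.976 for libraries 1 and 2, 1 and 3, and 2 and 3. The chi-square per degree of freedom between the same sums was 451, 820 and 494, so they were not copies of each other.

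Choices of tests, filters, cell type markers, gene lists and the rule for named genes were made before the data were examined. Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs, which left 3575, 25543 and 15155 barcodes (88.0%, 90.4% and 88.0%). Doublets were scored as the share of simulated doublets among the nearest neighbours and removed at 0.8% per 1000 barcodes, capped at 20%: 116, 5109 and 2088 barcodes, at rates of 3.25%, 20% and 13.8%. Each library was clustered on its own, so no integration was needed: counts scaled to 10000 per cell, log-transformed, 1500 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, which gave 13, 17 and 14 clusters. Clustering used 16301 genes, those with an even last digit in the Ensembl identifier plus the markers, without any gene of the lists and without mitochondrial, ribosomal, immunoglobulin and T cell receptor variable genes and 102 sex-linked genes. The other 17237 genes were held out, and results on named genes use held-out genes only. Held-out genes were measured in the same cells and can vary together with the clustering genes. Their p-values therefore do not test whether the groups exist.

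Clusters were named from markers of 12 cell types. A name needed 3 markers detected in 20% of the cells, and a cluster stayed unnamed when its 10 leading genes held at least 1 marker of another type and as many of that type as of its own, or when it had few UMIs and no marker of its own among them. Mesothelial-like cells of the 3 libraries were subclustered together on genes scaled within each library, with 20 principal components, 15 neighbours and Leiden resolution 0.4.

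Raw counts were summed per library and class. The 4 classes with at least 20 cells in every library entered 1 fit: mesothelial-like, fibroblast-like, myeloid-like and T_NK-like. Summed UMIs in libraries 1, 2 and 3 were 52768718, 125143513 and 115258941 for mesothelial-like, 3972005, 11136205 and 975615 for fibroblast-like, 828740, 2717790 and 2918087 for myeloid-like and 2472224, 2202073 and 1230664 for T_NK-like cells. Tests were edgeR quasi-likelihood tests with TMM factors, filterByExpr and the library as a block, with Benjamini-Hochberg adjustment at 0.05. The classes of a library come from the same sample, so the block follows from the library itself. Subclusters were compared in the same way, each with the mean of the others. CPM beside a test are TMM-scaled, and levels per library are plain CPM of the sums. The SE beside a log2 difference was worked out from the test, as the absolute difference divided by the square root of the quasi-likelihood F statistic. It is not the spread of the log2 ratios over the 3 libraries. A planned comparison with endothelial-like cells was not made, since no cluster carried that name.

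Genes are named by a fixed rule: the 8 held-out genes with the largest positive and the 8 with the largest negative log2 difference (4 and 4 for subclusters) among those with an adjusted p under 0.05, an absolute log2 difference of at least 1, an average log2 CPM of at least 5 and the same direction in every library. From each list, up to 4 members past the adjusted p with the largest absolute difference are named for the fibroblast comparison and up to 2 for the others. Clone-named, mitochondrial, ribosomal, immunoglobulin, T cell receptor, sex-linked and genotype-revealing genes were left out of the naming. For 2 genes that the rule names, the results are not reported here. The 13 lists hold 202 genes: epithelial junction, mesenchymal, basement membrane, complement, chemokine and cytokine, hyaluronan and fluid, retinoid, adipogenic and lipid, growth factor and binding protein, antigen presentation and interferon, immediate early and heat shock, metallothionein and oxidative, and proliferation. Lists were tested with camera at a preset correlation of 0.01, with the estimated correlation beside it, and with fry; members were counted by the edgeR test over all genes and adjusted over the list alone.

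Alternatives were RLE size factors, no filter on low counts, no library block, DESeq2's Wald test, only the 2 classes compared in the fit, doublets kept, a mitochondrial limit of 10%, a minimum of 1000 UMIs, Leiden resolutions of 0.5 and 2.0 (0.2 for subclusters), clustering on all genes and leaving out each library in turn. After the data were seen, 3 more were added: mesothelial-like sums without subclusters 6 and 7, sums with the estimated mesothelial RNA subtracted, and subcluster 5 without cycling cells.

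The tests were tested on simulated data in which 200 genes were changed. For the comparisons with fibroblast-like, myeloid-like and T_NK-like cells, 10%, 7% and 5% of genes changed 2-fold and 76%, 76% and 74% of genes changed 4-fold were recovered. For subclusters 1 to 7 the recovery at 2-fold was 95%, 95%, 98%, 89%, 84%, 32% and 73%. All recovered genes had the right direction, and at most 0.170% of unchanged genes were called. The counts were simulated from a single mean per gene with the measured totals and dispersions. Differences between libraries, and between the other classes, were not simulated, and only genes above a minimum level were changed. These shares therefore describe simpler data than the measured ones. Tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.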

Results

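The series holds single-cell RNA counts from 3 libraries of human omental adipose tissue, the visceral fat depot that hangs from the stomach. Its surface is lined by mesothelial cells, a flat epithelium of mesodermal origin, and the labels name a mesothelial cell isolation procedure for every library. All 3 libraries carry the same labels and form 1 group, so the comparisons the design allows are between cell classes within libraries and between subclusters of the mesothelial-like cells. The labels do not say whether the libraries came from separate donors. With the library as a block, p-values rest on how class or subcluster differences varied between these libraries, which may be technical. That spread was estimated over all sums in a fit, those of classes outside a comparison included. The deposited matrices held 4061, 28243 and 17223 barcodes in libraries 1, 2 and 3, with 68868423, 231616640 and 180378103 UMIs (unique molecular identifiers, 1 per captured transcript). The median barcode held 8400, 5367 and 7302 UMIs. After filters on UMIs, genes, mitochondrial share and doublets, 3459, 20434 and 13067 cells remained. Cell classes were rebuilt from marker genes and are written "X-like". The 95% intervals are exact Clopper-Pearson intervals. Intervals and limits for counts of 0 cover counting error only.

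Mesothelial-like cells made up most of every library. Most of their clusters were led by keratins (KRT8, KRT18, KRT19), the lectin ITLN1, the uroplakin UPK3B and mesothelin (MSLN), and they held 72.3% ± 13.6 of cells (SD, n = 3). The share was 62.2% (60.5 to 63.8) in library 1, 67.0% (66.3 to 67.6) in library 2 and 87.8% (87.2 to 88.3) in library 3. Fibroblast-like cells, which had LUM and MFAP5 among the 10 leading genes of each cluster, held 12.3% (11.2 to 13.4), 16.4% (15.9 to 16.9) and 1.75% (1.53 to 1.99), with a mean of 10.1% ± 7.54. T_NK-like cells, which carried T cell receptor chains or the cytotoxic genes NKG7 and GNLY, held 20.1% (18.8 to 21.5), 7.33% (6.98 to 7.70) and 5.56% (5.18 to 5.97), with a mean of 11.01% ± 7.94. Myeloid-like cells, led by LYZ, C1QA or S100A8, held 4.22% (3.58 to 4.95), 5.49% (5.18 to 5.81) and 4.68% (4.32 to 5.05), with a mean of 4.79% ± 0.641. With a mitochondrial limit of 10% the shares were 16.7%, 27.6% and 6.48% for fibroblast-like cells (mean 16.9%), 16.8%, 9.91% and 11.6% for T_NK-like cells and 3.51%, 7.22% and 10.3% for myeloid-like cells. With doublets kept, T_NK-like cells held 2.94% of library 2. Unnamed clusters then held 8.62% of library 2 and 5.16% of library 3, against 0% of each in the planned setting. Part of the cells thus had no class name in that setting. The mean of T_NK-like cells was 6.45% without library 1, and that of fibroblast-like cells 7.02% without library 2 and 14.3% without library 3. No cluster was named adipocyte-like, endothelial-like, lymphatic endothelial-like, mural-like or erythroid-like in any library. For a count of 0 cells in such clusters, a floor of 3 cells is 0.0867%, 0.0147% and 0.0230% of libraries 1, 2 and 3. The exact upper limits were 0.107%, 0.0181% and 0.0282%. Both leave out cells within other clusters. An unnamed cluster of 15 cells in library 1 (0.434%) was led by CCL21, PPBP, FABP4, PF4, TFF3 and CLDN5. The isolation procedure selects cells, so these shares describe the isolates and not the tissue.

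**Figure D1:**
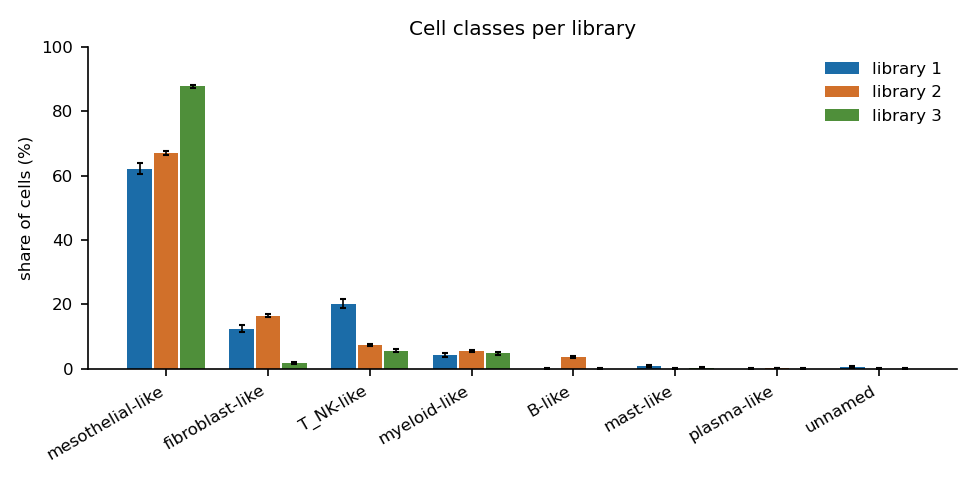
Share of cells (%, vertical axis) in each cell class for the 3 libraries, as bars with exact 95% binomial intervals. Mesothelial-like cells were the largest class in every library, from 62.2% in library 1 to 87.8% in library 3.

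RNA of mesothelial markers was also read in the other classes, and to different extents in the 3 libraries. The median of 20 mesothelial markers in T_NK-like cells stood at 0.733% of the mesothelial-like level in library 1, 26.6% in library 2 and 9.09% in library 3. In myeloid-like cells the values were 1.89%, 19.0% and 4.60%, and in fibroblast-like cells 1.44%, 11.5% and 13.5%. ITLN1, the most abundant marker of library 2, had at least 1 UMI in 93.4% of the T_NK-like cells of that library (median 1200.5 UMIs per cell) and in 99.9% of its mesothelial-like cells (median 6736), so a UMI of ITLN1 there did not tell the classes apart. In the opposite direction, the median fibroblast marker in mesothelial-like cells stood at 1.96%, 1.91% and 2.60% of its fibroblast-like level.

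**Figure D2:**
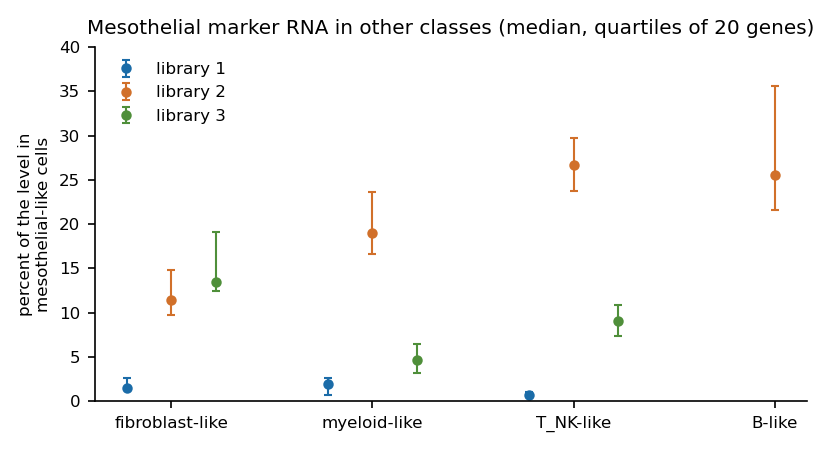
Level of mesothelial marker RNA in other cell classes as a percent of the level in mesothelial-like cells of the same library, with points for the median and bars for the quartiles over 20 markers. The T_NK-like cells of library 2 stood at 26.6%, against 0.733% in library 1 and 9.09% in library 3.

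The main comparison asked which genes separate mesothelial-like from fibroblast-like cells, the other stromal class of these isolates. Mesothelial-like cells held more RNA of FGF1, the acidic fibroblast growth factor, at 186 ± 35.2 CPM against 10.8 ± 10.0 (UMIs as parts of the summed total, TMM-scaled, SD, n = 3). TFPI2, a secreted inhibitor of serine proteases, stood at 1435 ± 198 against 109 ± 59.0. Mesothelial markers stood at a median of 1.44%, 11.5% and 13.5% of their mesothelial-like level in fibroblast-like cells of libraries 1, 2 and 3. The fibroblast-like levels of FGF1, TFPI2 and the other genes higher in mesothelial-like cells were not told apart from such RNA. Fibroblast-like cells held more of CFD, the complement protease adipsin, at 18999 ± 3042 CPM against 42.6 ± 25.8 in mesothelial-like cells, and of SCARA5, a ferritin receptor, at 483 ± 136 against 1.38 ± 1.53. Most called genes of the junction list were higher in mesothelial-like cells and most of the mesenchymal and basement membrane lists lower; no list passed with an estimated correlation. Of 6297 genes held out of the clustering and tested, 1324 passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05: 695 higher and 629 lower in mesothelial-like cells.

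Among genes with an average log2 CPM of at least 5, as the rule for named genes asks, the 8 with the largest positive differences were FGF1 (log2 difference 4.93 ± 0.79 SE), the hydroxysteroid dehydrogenase HSD17B6 (4.88 ± 0.79), the protein cross-linking enzyme TGM1 (4.74 ± 0.99), the junctional adhesion receptor CXADR (4.73 ± 0.90), the lipoxygenase ALOX15 (4.37 ± 0.79), MCTP2 (4.24 ± 0.67), the water channel AQP1 (4.21 ± 0.88) and TFPI2 (4.20 ± 0.74). Their edgeR adjusted p lay between 0.00173 and 0.00767, and each was higher in 3 of 3 libraries. Without library 3, CXADR, AQP1 and TFPI2 no longer passed (edgeR adjusted p = 0.0507, 0.0735 and 0.0513, with log2 differences that stayed positive in the 2 remaining libraries). With doublets kept, none of these 8 genes passed: the log2 differences lay between 2.18 and 3.01 and the edgeR adjusted p between 0.115 and 0.18. The 8 with the largest negative differences at that abundance were the serine protease HTRA3 (-9.86 ± 0.97), SCARA5 (-9.17 ± 0.79), the secreted glutathione peroxidase GPX3 (-9.12 ± 0.80), CFD (-9.06 ± 0.94), the secreted Wnt antagonist SFRP4 (-8.73 ± 0.84), the matrix protein ECM1 (-7.80 ± 0.71), the basement membrane linker NID1 (-7.73 ± 0.54) and the Ras-related protein RASD1 (-7.52 ± 0.91). Each was lower in 3 of 3 libraries, with an edgeR adjusted p between 2.19e-05 and 0.000413.

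**Figure D3:**
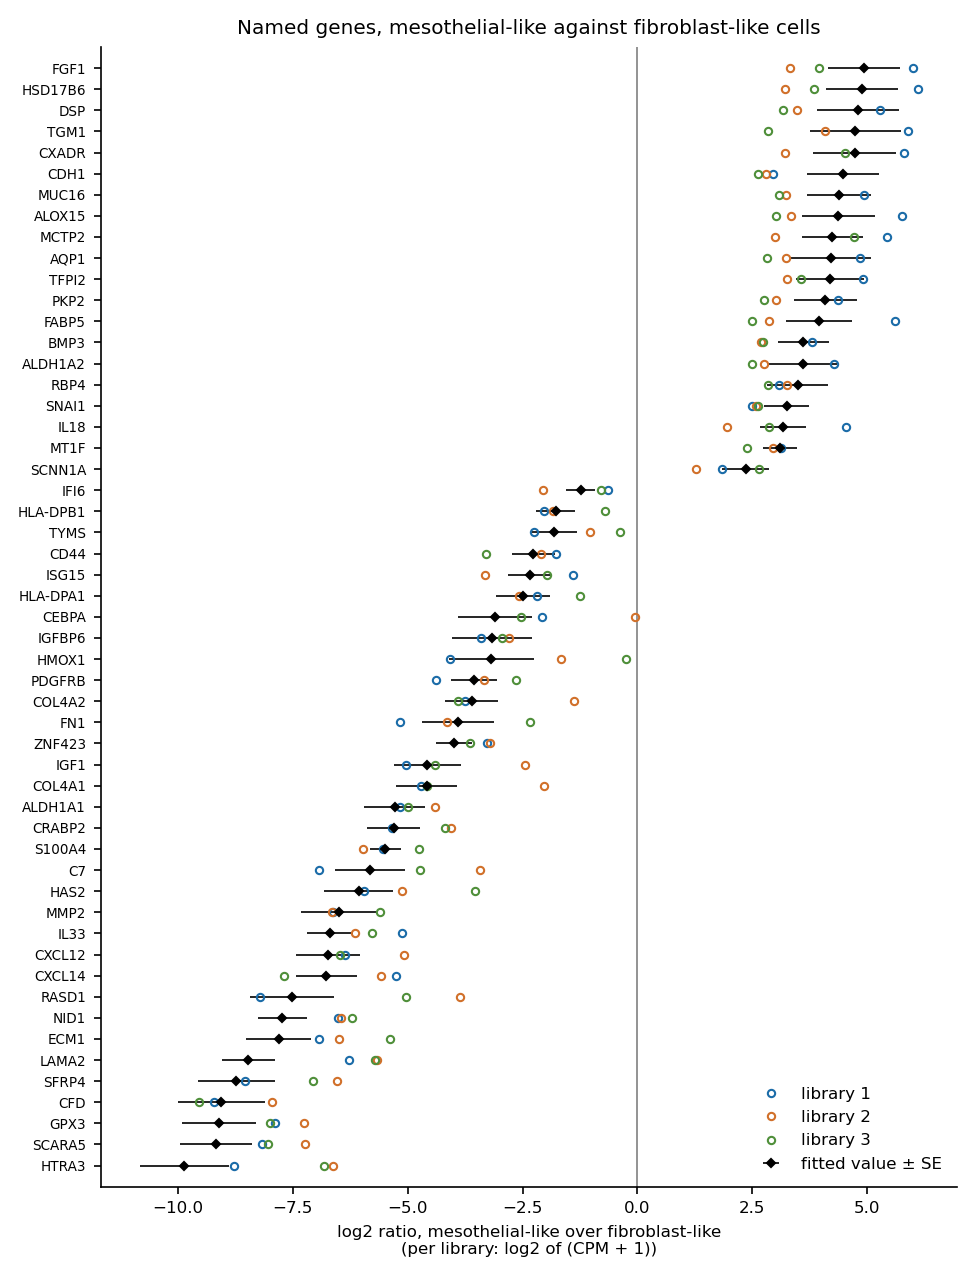
Log2 difference between mesothelial-like and fibroblast-like cells (horizontal axis) for every gene named by the fixed rule. Black marks are the edgeR estimate ± an SE worked out from the F statistic of the test. Small points are the log2 ratio of CPM + 1 in each library. FGF1 stands at 4.93 and HTRA3 at -9.86.

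Epithelial junction genes were the list most clearly set apart from fibroblast-like cells. Of 14 members tested, 12 were higher and 0 lower (12 and 0 adjusted over the list alone), with camera adjusted p = 5.95e-09, and adjusted p = 0.664 with an estimated correlation. The desmosomal plaque protein DSP was higher by 4.80 ± 0.89 on the log2 scale and E-cadherin (CDH1) by 4.48 ± 0.77. The difference of the membrane mucin MUC16 was 4.38 ± 0.69 and that of the plakophilin PKP2 4.09 ± 0.69 (edgeR adjusted p = 0.00406, 0.00284, 0.00178 and 0.00246; 3 of 3 libraries each). With doublets kept these 4 did not pass, with log2 differences of 2.70, 2.25, 2.67 and 2.16 (edgeR adjusted p = 0.135, 0.088, 0.11 and 0.133). CDH1 was scarce all the same, at 8.68 ± 4.83 CPM.

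The mesenchymal list went mostly the other way, with 8 of 18 members lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.00281, and adjusted p = 0.664 with an estimated correlation). The gelatinase MMP2 differed by -6.50 ± 0.82, the calcium-binding protein S100A4 by -5.48 ± 0.33 and fibronectin (FN1) by -3.91 ± 0.78, each in 3 of 3 libraries (edgeR adjusted p = 0.00052, 1.43e-05 and 0.00602). SNAI1, a transcription factor known as a repressor of E-cadherin, was the member that was higher, by 3.25 ± 0.48 (edgeR adjusted p = 0.00131, 3 of 3 libraries), but did not pass with doublets kept (1.96, edgeR adjusted p = 0.12). Vimentin (VIM) was lower by far less, with a log2 difference of -0.93, and its level in mesothelial-like cells was still 2007 ± 1101 CPM.

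Basement membrane genes split by chain. Of 13 tested, 7 were lower and 2 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.664 with an estimated correlation). The laminin chain LAMA2 differed by -8.47 ± 0.58, NID1 by -7.73 ± 0.54 and the collagen IV chains COL4A1 and COL4A2 by -4.58 ± 0.66 and -3.60 ± 0.58 (edgeR adjusted p from 2.19e-05 to 0.00227, 3 of 3 libraries each). The 2 higher members were the laminin chain LAMA5 (2.05) and the heparan sulfate proteoglycan AGRN (1.36).

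The other lists held called members in both directions and did not pass as lists. In the complement list, CFD and the terminal component C7 (-5.81 ± 0.76) were lower and 12 of 14 members did not pass (2 higher and 2 lower adjusted over the list alone). Its median was 0.16, its mean -0.82 and camera pointed down (adjusted p = 0.854). Of 15 chemokines and cytokines, CXCL14 (-6.77 ± 0.67), the chemokine CXCL12 (-6.74 ± 0.70) and the alarmin IL33 (-6.68 ± 0.50) were among 4 lower and IL18 (3.17 ± 0.50) was the 1 higher (3 and 6 higher and lower adjusted over the list alone; camera adjusted p = 0.185). The hyaluronan synthase HAS2 (-6.07 ± 0.75) and the hyaluronan receptor CD44 (-2.27 ± 0.46) were lower, and AQP1 and the sodium channel subunit SCNN1A (2.35 ± 0.50) higher, among 11 hyaluronan and fluid genes (2 and 2 adjusted over the list alone; camera adjusted p = 0.994, median 0.19, mean -0.06, camera up and fry down). Of 10 retinoid genes, the retinaldehyde dehydrogenase ALDH1A2 (3.60 ± 0.76) and the retinol carrier RBP4 (3.49 ± 0.66) were among 3 higher, and CRABP2 (-5.31 ± 0.58) and ALDH1A1 (-5.28 ± 0.66) among 3 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.994). Each of these genes had its direction in 3 of 3 libraries, with an edgeR adjusted p between 3.15e-05 and 0.00844. Without library 3, ALDH1A2 and CD44 no longer passed (edgeR adjusted p = 0.0692 and 0.0502). SCNN1A did not pass without library 1 or library 2 (0.0673 and 0.0678), nor CD44 without library 2 (0.0556). With doublets kept, IL18, ALDH1A2 and RBP4 did not pass (edgeR adjusted p = 0.12, 0.119 and 0.145).

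Among 11 adipogenic and lipid genes, the fatty acid binding protein FABP5 (3.95 ± 0.72) was among 2 higher, and ZNF423 (-3.99 ± 0.38), a regulator of preadipocyte commitment, PDGFRB (-3.56 ± 0.50) and CEBPA (-3.11 ± 0.81) were among 4 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.0711). Of 19 growth factors and binding proteins, FGF1 and BMP3 (3.61 ± 0.55) were among 4 higher, and IGF1 (-4.58 ± 0.73) and IGFBP6 (-3.17 ± 0.88) among 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.994, up, with a median of -0.62, a mean of -0.13 and fry down). Antigen presentation and interferon genes were lower in 4 of 19 and higher in 0 (4 and 0 adjusted over the list alone; camera adjusted p = 0.373): HLA-DPA1 (-2.48 ± 0.59), ISG15 (-2.34 ± 0.48), HLA-DPB1 (-1.78 ± 0.42) and IFI6 (-1.24 ± 0.32). The metallothionein MT1F was higher (3.1 ± 0.37) and GPX3 and the haem oxygenase HMOX1 (-3.18 ± 0.93) lower among 13 metallothionein and oxidative stress genes (2 and 2 adjusted over the list alone; camera adjusted p = 0.854, up, with a median of 0.08 and a mean of -0.32). The thymidylate synthase TYMS (-1.82 ± 0.52) was the 1 of 9 proliferation genes that passed, lower (1 adjusted over the list alone; camera adjusted p = 0.909). Of 16 immediate early and heat shock genes, 0 passed in edgeR or adjusted over the list alone (camera adjusted p = 0.752). The named members had their direction in 3 of 3 libraries and an edgeR adjusted p between 7.13e-05 and 0.0368. With doublets kept, FABP5, CEBPA, BMP3, IGFBP6, HLA-DPB1, HMOX1 and TYMS did not pass (edgeR adjusted p from 0.0757 to 0.147).

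Several of these smaller differences lost their call when 1 library was left out. Without library 1, CEBPA and TYMS did not pass (edgeR adjusted p = 0.121 and 0.208). Without library 2, ISG15, HLA-DPB1, IFI6, HMOX1 and TYMS did not (0.0805, 0.0506, 0.283, 0.0685 and 0.113), and without library 3, CEBPA, IGFBP6, HLA-DPA1, HLA-DPB1, IFI6 and HMOX1 did not (0.161, 0.193, 0.057, 0.0649, 0.104 and 0.11). The log2 differences kept their sign. The number of genes past the threshold was 632 without library 2 and 737 without library 3, 804 with no library block, 2086 with only these 2 classes in the fit and 470 (85 higher, 385 lower) with doublets kept, where 23 of the 53 named genes did not pass (edgeR adjusted p from 0.0757 to 0.18). With the share of mesothelial RNA estimated from the markers taken off the fibroblast-like sums, 1429 genes passed.

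Against myeloid-like cells, the question was what distinguishes the mesothelium from the phagocytes of the isolate. Mesothelial-like cells held more RNA of TGM1, of the calcium-binding protein S100A16, of TFPI2 and of the secreted phospholipase PLA2G2A, at 1490 ± 1146 CPM against 75.8 ± 59.5. Myeloid-like cells held more of the macrophage pore-forming protein MPEG1, at 148 ± 30.9 CPM against 0.114 ± 0.161, and of MS4A6A, at 842 ± 264 against 1.05 ± 1.13. Growth factor, junction, complement and basement membrane lists were higher in mesothelial-like cells and antigen presentation genes lower by camera at the preset correlation, and none passed with an estimated one (adjusted p = 0.712 for each). Of 6297 genes, 2802 passed edgeR's test, 1382 higher and 1420 lower.

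At an average log2 CPM of at least 5, the 8 largest positive log2 differences were TGM1 (4.81 ± 1.00), S100A16 (4.54 ± 0.92), TFPI2 (4.52 ± 0.77), PLA2G2A (4.50 ± 1.01), AQP1 (4.36 ± 0.90), the growth factor binding protein IGFBP3 (4.33 ± 1.07), the proteoglycan-cleaving protease ADAMTS4 (4.30 ± 1.25) and ADIRF (4.29 ± 0.89), with edgeR adjusted p between 0.00131 and 0.0189 and the same direction in 3 of 3 libraries. The 8 largest negative ones were MPEG1 (-10.64 ± 0.81), MS4A6A (-10.49 ± 0.89), SMIM25 (-10.28 ± 0.64), the beta-glucan receptor CLEC7A (-10.21 ± 0.61), the ribonuclease RNASE6 (-10.20 ± 0.86), MS4A4A (-10.01 ± 0.97), the complement receptor VSIG4 (-9.96 ± 0.84) and the scavenger receptor MSR1 (-9.91 ± 0.77), in 3 of 3 libraries with edgeR adjusted p between 2.51e-06 and 3.2e-05. The mesothelial RNA read in myeloid-like cells was 19.0% of the mesothelial-like level in library 2 against 1.89% in library 1. For TGM1, given as an example, the log2 ratio was 7.68 in library 1, 2.64 in library 2 and 5.45 in library 3. A relation between the 2 over all positive differences was not tested. Without library 3, S100A16, PLA2G2A, AQP1, ADAMTS4 and ADIRF did not pass, nor did DSP, TJP1, TWIST1, LAMA4, HSPG2, CXCL8, HAS1, RARRES2, JUN and TOP2A named below (edgeR adjusted p from 0.0605 to 0.274). With doublets kept, 20 of the 39 named genes did not pass, these 8 higher genes among them and, of those named below, DSP, TJP1, TWIST1, LAMA4, HSPG2, CFB, HAS1, RARRES2, FGF1, JUN, MKI67 and TOP2A (edgeR adjusted p from 0.0768 to 0.567).

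Of 14 junction genes 11 were higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 0.000622), with DSP at 4.34 ± 0.89 and the tight junction scaffold TJP1 at 4.18 ± 1.07. Growth factors and binding proteins were higher in 15 of 19 and lower in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 0.000407), among them IGFBP3 and FGF1 (4.28 ± 0.78). Complement genes were higher in 8 of 14 and lower in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0281): factor B (CFB) was higher by 4.40 ± 0.73 and CFD differed by -5.11 ± 0.80. Basement membrane genes were higher in 8 of 13 and lower in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0281), led by the laminin chain LAMA4 (4.04 ± 0.83) and perlecan (HSPG2, 3.60 ± 0.79). Antigen presentation genes were lower in 12 of 19 and higher in 0 (12 and 1 adjusted over the list alone; camera adjusted p = 0.000407). HLA-DPA1 differed by -9.18 ± 0.78 and HLA-DRA by -8.79 ± 0.78. These 5 list calls were lost otherwise (adjusted p = 0.712 with an estimated correlation for each). The named members had their direction in 3 of 3 libraries with an edgeR adjusted p between 1.35e-05 and 0.0104.

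The remaining 8 lists did not pass. Retinoid genes were higher in 7 of 10 and lower in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0672). RARRES2 differed by 4.28 ± 0.94 and ALDH1A1 by -5.53 ± 0.67. Mesenchymal genes were higher in 9 of 18 and lower in 4 (9 and 5 adjusted over the list alone; camera adjusted p = 0.591). TGFBI differed by -5.23 ± 0.96. The transcription factor TWIST1, with 635 UMIs in mesothelial-like and 0 in myeloid-like cells, was at least 4.67-fold higher against a floor of 3 counts over the group. TWIST1 (edgeR adjusted p = 0.0259, 3 of 3 libraries) did not pass without library 1 (0.0522), library 2 or library 3. Of 15 chemokines and cytokines, 7 were lower and 4 higher (7 and 5 adjusted over the list alone; camera adjusted p = 0.747). CXCL3 differed by -6.53 ± 1.37 and CXCL8 by -6.27 ± 1.29. The hyaluronan synthase HAS1 (3.68 ± 1.20) and AQP1 were among 6 of 11 hyaluronan and fluid genes that were higher, with 1 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.18). The scavenger receptor CD36 (-8.58 ± 0.57) and CEBPA (-6.47 ± 0.77) were among 5 of 11 adipogenic and lipid genes that were lower, with 1 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.18). HMOX1 (-7.15 ± 1.06) and GPX3 (-4.48 ± 0.70) were among 3 of 13 metallothionein and oxidative genes that were lower, with 4 higher (3 and 4 adjusted over the list alone; camera adjusted p = 0.747, up, with a median of 0.0027, a mean of -0.14 and fry down). Of 16 immediate early genes JUN was higher (0.68 ± 0.23) and 0 passed adjusted over the list alone (camera adjusted p = 0.62). Proliferation genes were lower in 6 of 9 (7 adjusted over the list alone; camera adjusted p = 0.18). MKI67 differed by -3.97 ± 1.02 and TOP2A by -3.07 ± 0.75, both lower in 2 of 3 libraries. The edgeR adjusted p of the named members lay between 3.5e-06 and 0.0355. Without library 2, JUN, MKI67 and TOP2A did not pass (TWIST1 included, 0.0512 to 0.173). The number of genes past the threshold was 1844 without library 2, 1169 without library 3 and 1100 (138 higher, 962 lower) with doublets kept.

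Against T_NK-like cells, mesothelial-like cells again held more TGM1 (log2 difference 4.44 ± 0.97), AQP1 (4.26 ± 0.93), the collagen cross-linking enzyme LOX (4.15 ± 0.90), the esterase AADAC (4.14 ± 0.92), PLA2G2A (4.11 ± 1.02), the amino acid transporter SLC7A2 (4.10 ± 1.10), S100A16 (4.06 ± 0.92) and TFPI2 (4.05 ± 0.76). T_NK-like cells held more of the granzymes GZMB (-11.00 ± 0.98) and GZMA (-10.95 ± 0.80), the T cell receptor signalling chain CD247 (-10.73 ± 0.61), the cathepsin CTSW (-10.65 ± 0.51), the adaptor SKAP1 (-10.32 ± 0.65), CYTIP (-10.07 ± 0.77), the chemokine CCL5 (-10.06 ± 0.67) and the transcription factor PRDM1 (-9.94 ± 0.68). GZMA stood at 1032 ± 570 CPM against 0.494 ± 0.157. Each direction was seen in 3 of 3 libraries, with edgeR adjusted p from 0.0025 to 0.0134 for the higher and from 1.12e-06 to 2.02e-05 for the lower genes. Of 6297 genes, 2790 passed, 1409 higher and 1381 lower. Mesothelial RNA in T_NK-like cells stood at 26.6% of the mesothelial-like level in library 2 and 0.733% in library 1. For AQP1, given as an example, the log2 ratio was 7.03 in library 1, 2.22 in library 2 and 3.05 in library 3. Here too, a relation over all positive differences was not tested. Without library 3, AQP1, LOX, AADAC, PLA2G2A, SLC7A2 and S100A16 did not pass, nor did DSP, COL4A2, LAMA4, C3, LIF, CXCL1, HAS1, ALDH1A3, RARRES1, PPARG, IGFBP5, IER3, EGR1, MT1E, MT1M and TOP2A named below (edgeR adjusted p from 0.0506 to 0.189), and SLC7A2 did not pass without library 1 (0.0607).

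Junction genes were higher in 13 of 14 and lower in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 0.000112), among them MUC16 (4.06 ± 0.70) and DSP (3.85 ± 0.86). Growth factors and binding proteins were higher in 16 of 19 and lower in 0 (17 and 0 adjusted over the list alone; camera adjusted p = 0.000112). BMP2 differed by 4.77 ± 0.84 and IGFBP5 by 3.99 ± 1.04. Complement genes were higher in 10 of 14 and lower in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 0.00101), with CFB at 4.81 ± 0.77 and C3, the central complement component, at 4.03 ± 0.90. Basement membrane genes were higher in 10 of 13 and lower in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 0.00527), with LAMA4 at 3.71 ± 0.81. COL4A2, with 500 UMIs against 1, had a ratio of 10.1 with a counting interval of 1.80 to 399. Retinoid genes were higher in 7 of 10 and lower in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0252). ALDH1A3 differed by 4.01 ± 1.00 and RARRES1 by 3.94 ± 0.91. Antigen presentation genes were lower in 12 of 19 and higher in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0213). HLA-DPA1 differed by -5.12 ± 0.66 and HLA-DPB1 by -4.59 ± 0.46. The 6 list calls were lost otherwise (adjusted p = 0.477 with an estimated correlation for each). Named members had their direction in 3 of 3 libraries and an edgeR adjusted p between 4.71e-05 and 0.0447. COL4A2 did not pass without library 1 (0.349).

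Of the 7 lists that did not pass, 3 lay near the threshold. The mesenchymal list had 9 of 18 members higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.051): SNAI1 was higher by 4.16 ± 0.62 and S100A4 differed by -4.49 ± 0.31. Hyaluronan and fluid genes were higher in 7 of 11 and lower in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0508), with AQP1 and HAS1 (3.65 ± 1.26). Metallothionein and oxidative genes were higher in 7 of 13 and lower in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.051). MT1E differed by 3.60 ± 0.80 and MT1M by 3.5 ± 0.99. Chemokines and cytokines were higher in 5 of 15 and lower in 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.11). LIF differed by 4.75 ± 1.13 and CXCL1 by 3.99 ± 1.21. In the adipogenic and lipid list 4 of 11 were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.304). CEBPA differed by -3.58 ± 0.87. PPARG, the adipogenic nuclear receptor, had 605 UMIs against 1, a ratio of 12.2 with a counting interval of 2.18 to 482. Immediate early genes were higher in 3 of 16 and lower in 0 (1 and 0 adjusted over the list alone; camera adjusted p = 0.219). IER3 differed by 2.74 ± 0.88 and EGR1 by 2.40 ± 0.77. Proliferation genes were lower in 5 of 9 and higher in 0 (6 and 1 adjusted over the list alone; camera adjusted p = 0.136). MKI67 differed by -3.89 ± 1.06 and TOP2A by -2.72 ± 0.78. Named members had their direction in 3 of 3 libraries and an edgeR adjusted p between 4.34e-06 and 0.0385. PPARG and CEBPA did not pass without library 1 (0.298 and 0.214), nor TOP2A without library 2 (0.0786). The number of genes past the threshold was 1404 without library 3 and 644 (18 higher, 626 lower) with doublets kept, where 30 of the 41 named genes did not pass: all but S100A4, HLA-DPA1, HLA-DPB1 and the 8 that T_NK-like cells held more of, from GZMB to PRDM1 (edgeR adjusted p from 0.0982 to 0.763).

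The mesothelial-like cells themselves split into 7 subclusters, each present in all 3 libraries and compared by number with the mean of the other 6. Each subcluster had the same weight in that mean, whatever its number of cells. A gene high in 1 rare subcluster can thus be called lower in the others. APOE stood at 312 CPM in subcluster 5, within a mean of 57.5 for the subclusters that subcluster 2 was compared with. HLA-DPA1 stood at 44.1 CPM in subcluster 6, within a mean of 14.1 for the same comparison. Such lower calls in subclusters 2, 3 and 4 were not told apart from this, among them APOE, MMP2, CFD and HLA-DPA1. The same holds in subcluster 3 for the mesenchymal genes, CD44, ALDH1A1 and HLA-DRA. Of 6537 genes tested with edgeR, the number past the threshold was 0 in subcluster 1, 85 in subcluster 2, 399 in subcluster 3, 1112 in subcluster 4, 1022 in subcluster 5, 84 in subcluster 6 and 5 in subcluster 7. Subcluster 1, with 473, 4482 and 5582 cells in libraries 1, 2 and 3, had 762 genes at an unadjusted p under 0.05 in edgeR, and DESeq2 called 33. Without any difference, a share of about 0.05 of the 6537 genes would have such a p. The counts given below for subclusters 2, 3 and 4 with no library block lie under that share.

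Subcluster 5 was rare. It held 32, 77 and 455 cells, which is 1.49% (1.02 to 2.09), 0.563% (0.444 to 0.703) and 3.97% (3.62 to 4.34) of the mesothelial-like cells. The lipid carrier APOE stood at 312 ± 160 CPM against 6.05 ± 4.82 in the other subclusters, a log2 difference of 6.23 ± 0.31. Its log2 ratios of CPM + 1 were 7.73, 3.57 and 5.57 in libraries 1, 2 and 3, a spread that this SE does not describe. The matrix protein EGFL6 (3.62 ± 0.29) and FN1 (3.31 ± 0.27) were higher too. The protease inhibitor CST6 (-4.48 ± 0.42), the hedgehog-binding protein HHIP (-3.29 ± 0.28), the cytochrome CYP4B1 (-2.86 ± 0.39) and PCSK1N (-2.85 ± 0.28) were lower. These 7 had their direction in 3 of 3 libraries and an edgeR adjusted p between 1.05e-12 and 7.29e-06. Of the 1022 calls 587 were higher and 435 lower, and 247 genes passed with no library block.

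Mesenchymal genes were higher in 10 of 18 and lower in 1 in subcluster 5 (11 and 1 adjusted over the list alone), among them FN1, TWIST1 (4.19 ± 0.73), S100A4, ZEB2, SPARC, SNAI2, VIM, MMP2 and CDH11. TAGLN was the member that was lower. Complement C7 stood at 85.9 ± 56.6 CPM against 0.643 ± 0.453 (log2 difference 7.16 ± 0.28), IL33 at 35.7 ± 24.6 against 0.525 ± 0.719 (6.94 ± 0.51) and CXCL12 at 32.5 ± 16.3 against 1.90 ± 2.08 (4.19 ± 0.42). HAS2, at 93.9, 3.76 and 37.3 CPM against 0.23, 0.177 and 0.208, CD44 (1.94 ± 0.20), the retinoic acid binding protein CRABP2 (4.89 ± 0.39), PDGFRB (1.68 ± 0.27), COL4A2 (2.41 ± 0.38) and HLA-DRA (1.72 ± 0.27) were higher as well. CDH1 (-2.69 ± 0.69), MUC16 (-1.63 ± 0.22), FGF1 (-1.95 ± 0.24), BMP3 (-3.48 ± 0.40), FABP5 (-1.98 ± 0.28) and the complement regulator CD46 (-0.69 ± 0.15) were lower. All these had their direction in 3 of 3 libraries, with edgeR adjusted p from 5.39e-15 to 0.00809, but not to the same extent. In library 2, TWIST1 stood at 1.88 CPM in subcluster 5 against 1.78 in the other mesothelial-like cells, with log2 ratios of CPM + 1 of 2.96, 0.25 and 2.77 in libraries 1, 2 and 3. Those of HAS2 were 6.20, 1.05 and 5.08, and those of HLA-DRA 2.10, 0.086 and 1.11. Subcluster 5 held 77 cells in library 2, so the levels of TWIST1 and HAS2 there rest on very few UMIs. The direction of TWIST1 in library 2 is therefore not settled. TWIST1 and CDH1 did not pass without library 3 (adjusted p = 0.106 and 0.262).

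**Figure D4:**
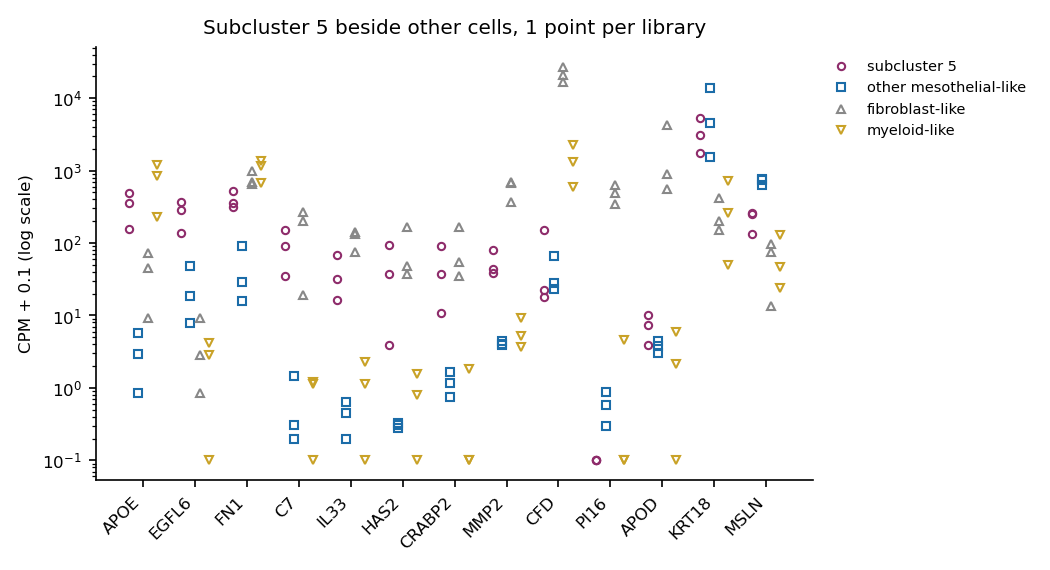
Level (CPM + 0.1, log axis) of selected genes in subcluster 5, the other mesothelial-like cells, fibroblast-like cells and myeloid-like cells, with 1 point per library. APOE and C7 stand higher in subcluster 5 than in the other mesothelial-like cells of every library, while PI16 and APOD stay far below the fibroblast-like level.

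Proliferation genes were higher in 11 of 12 in subcluster 5 (12 adjusted over the list alone). MKI67 stood at 4.40, 48.9 and 12.1 CPM in libraries 1, 2 and 3, against 0, 0.0562 and 0.0812 in the other mesothelial-like cells. The log2 ratio of CPM + 1 was 2.36, 5.39 and 3.62 for MKI67 and 2.95, 5.57 and 4.11 for CDK1 (edgeR adjusted p = 7.78e-11 and 9.64e-10). No fitted fold is given for these 2 genes, since their levels in the other subclusters lay near 0. Cells with at least 5 UMIs of this list made up 21.9% (7 of 32), 13.0% (10 of 77) and 3.74% (17 of 455) of subcluster 5, against 0.897%, 0.147% and 0.363% of the other mesothelial-like cells. In these cycling cells C7 stood at 6.03, 0 and 0 CPM in libraries 1, 2 and 3. In the other cells of subcluster 5 it stood at 44.6, 119 and 158 CPM. MMP2 stood at 133, 0 and 0 CPM against 64.0, 57.1 and 40.6, and VIM at 9048, 4044 and 2909 against 6680, 3361 and 2749. C7 and MMP2 were thus not read in the cycling cells of libraries 2 and 3, whereas VIM was. Smaller calls in subcluster 5 rested on library 3 or pointed 2 ways: NID1 (2.17 ± 0.58), ALDH1A1 (1.97 ± 0.32) and MT2A (0.74 ± 0.23) were higher in 2 of 3 libraries and, with GPX3 (1.96 ± 0.55) and ATF3 (0.89 ± 0.30), did not pass without library 3 (edgeR adjusted p = 0.767, 0.307, 0.789, 0.642 and 0.0584). HLA-DPA1 (1.12 ± 0.33) did not pass without library 1 or 2 (0.169 and 0.0864). The number of genes past the threshold was 478 without library 3. With doublets kept, no subcluster matched subcluster 5: the closest shared 25 cells with it (Jaccard index 0.0431). Its calls were therefore not repeated in that setting.

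Subcluster 4 held 69, 2669 and 96 cells, so most of it came from library 2. The chromatin protein HMGA1 (2.23 ± 0.32), the LIM protein FHL2 (2.16 ± 0.32), IGFBP3 (1.95 ± 0.29) and the microRNA host gene MIR222HG (1.82 ± 0.32) were higher, and the immediate early factors FOS (-1.64 ± 0.26) and ATF3 (-1.52 ± 0.39), TXNIP (-1.45 ± 0.35) and the kinase PDK4 (-1.36 ± 0.22) lower, in 3 of 3 libraries (edgeR adjusted p from 9.89e-05 to 0.00884). Hyaluronan and fluid genes were higher in 5 of 12 (7 adjusted over the list alone): the cyclooxygenase PTGS2 (1.80 ± 0.39), UGDH, which makes the UDP-glucuronate used for hyaluronan (1.58 ± 0.18), AQP1, AQP3 and CD44. LIF (1.68 ± 0.24), CD55 (1.03 ± 0.15), ALDH1A3 (1.39 ± 0.24), RDH10 (0.84 ± 0.17), NAMPT (0.99 ± 0.21), BMP2 (1.07 ± 0.22), SNAI2 (1.16 ± 0.33) and MUC16 (0.80 ± 0.16) were higher, and MMP2 (-1.13 ± 0.27), CFD (-0.74 ± 0.22), KLF15 (-1.38 ± 0.35), IFIT3 (-1.43 ± 0.44), HLA-DPB1 (-0.80 ± 0.26) and JUP (-0.66 ± 0.22) lower, each in 3 of 3 libraries (edgeR adjusted p from 2.46e-05 to 0.0436). CCL20 (3.45 ± 0.56) was higher in 2 of 3. The extent differed between libraries. Log2 ratios of CPM + 1 in libraries 1, 2 and 3 were 0.982, 0.579 and 0.00504 for SNAI2 and 0.118, 1.60 and 0.192 for PTGS2. Of 1112 calls 869 were higher and 243 lower (78.1% higher), and with RLE size factors 691 and 417 (62.4%). Without library 2, 3 genes passed and 23 of these 25 named genes did not, UGDH and CCL20 excepted (edgeR adjusted p from 0.0657 to 0.906). With no library block 0 passed, with 215 at an unadjusted p under 0.05. With doublets kept, ATF3, MUC16, JUP, MMP2, CFD and HLA-DPB1 did not pass (edgeR adjusted p from 0.0675 to 0.809). HLA-DPB1 did not pass without library 1 (0.169), nor JUP, KLF15 and IFIT3 without library 3 (0.115 to 0.169).

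Subcluster 3 held 428, 1912 and 2523 cells. The membrane protein DISP1 (1.41 ± 0.16), CST6 (1.27 ± 0.20), HHIP (1.11 ± 0.15) and ANGPTL7 (1.09 ± 0.18) were higher, and APOE (-2.41 ± 0.50), the growth factor AREG (-1.89 ± 0.34) and the chemokine CXCL2 (-1.88 ± 0.38) lower, in 3 of 3 libraries (edgeR adjusted p from 3.8e-05 to 0.00519). Mesenchymal genes were lower in 8 of 18 and higher in 0 (9 and 2 adjusted over the list alone), S100A4 (-1.17 ± 0.23) among them, and metallothionein and oxidative genes lower in 5 of 13 and higher in 0 (10 and 1 adjusted over the list alone), with GPX3 (-1.46 ± 0.40) and MT2A (-1.02 ± 0.26). CDH1 (1.03 ± 0.25), CGN (0.75 ± 0.13), LAMB1 (0.59 ± 0.11), BMP3 (1.19 ± 0.18) and FGF9 (1.05 ± 0.12) were higher, and CD44 (-1.14 ± 0.21), PTGS2 (-1.62 ± 0.47), ALDH1A1 (-1.38 ± 0.30), HLA-DRA (-1.57 ± 0.25), HLA-DPA1 (-0.90 ± 0.22), CFD (-0.79 ± 0.18), CD55 (-0.70 ± 0.17), IER3 (-0.96 ± 0.23) and JUND (-0.51 ± 0.14) lower, in 3 of 3 libraries (edgeR adjusted p up to 0.0405). CXCL3 (-1.84 ± 0.37) was lower in 2 of 3. CD44 stood at 216 CPM in subcluster 5, within a mean of 93.2 for the subclusters compared. HLA-DRA stood at 110 CPM in subcluster 6, within a mean of 37.5. Mesenchymal genes and ALDH1A1 were also called higher in subcluster 5. These lower calls were thus not told apart from the weight of those rare subclusters in the mean. Of 399 calls 269 were higher and 130 lower (67.4% higher), and with RLE size factors 243 and 204 (54.4%).

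Many of these calls of subcluster 3 were lost when 1 library was left out. Without library 1, CXCL2, CXCL3, HLA-DPA1 and GPX3 did not pass (edgeR adjusted p from 0.0599 to 0.924). Without library 2, 13 of the genes above did not (APOE, CDH1, CGN, CFD, CD55, CXCL3, PTGS2, ALDH1A1, HLA-DPA1, IER3, JUND, GPX3 and MT2A; 0.0597 to 0.974). Without library 3, 10 did not (APOE, CDH1, LAMB1, CD55, PTGS2, ALDH1A1, IER3, JUND, GPX3 and MT2A; 0.0557 to 0.222). The number of genes past the threshold was 69 without library 2, 59 without library 3, 121 with doublets kept, where 12 of the genes above did not pass (edgeR adjusted p from 0.0505 to 0.556), and 0 with no library block, where 189 had an unadjusted p under 0.05.

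Subcluster 2, with 871, 4134 and 2645 cells, stood out by immediate early genes, which were higher in 6 of 16 (12 adjusted over the list alone): JUN, ATF3, EGR1, FOS, ZFP36 and FOSB. FOSB stood at 406 ± 174 CPM against 206 ± 104 (log2 difference 1.04 ± 0.12, edgeR adjusted p = 9.17e-05), and ATF3 (1.08 ± 0.27), AREG (1.35 ± 0.27) and the cytokine IL6 (1.05 ± 0.23) were higher and APOE lower (-1.93 ± 0.45), all in 3 of 3 libraries (edgeR adjusted p from 0.0112 to 0.0381). MUC16 (0.65 ± 0.14), CD55 (0.74 ± 0.15), FGF9 (0.63 ± 0.13), LAMB1 (0.43 ± 0.11), IL18 (0.42 ± 0.11) and HLA-E (0.46 ± 0.11) were higher, and MMP2 (-0.94 ± 0.21) and HLA-DPA1 (-1.03 ± 0.21) lower, also in 3 of 3 libraries (0.0111 to 0.0465). Of 85 calls 70 were higher and 15 lower (82.4% higher), and with RLE size factors 33 and 16 (67.3%), among which ATF3, LAMB1, IL18 and HLA-E were not (edgeR adjusted p from 0.0778 to 0.16). FOSB was the 1 named gene that passed without each of the libraries in turn, and the 1 that passed with doublets kept (edgeR adjusted p from 0.141 to 0.998 for the other 12, with 13 genes past the threshold). Without library 2, 12 of 13 did not pass (0.0522 to 0.594), without library 3, 9 did not (0.0779 to 0.398), and without library 1, IL6, MMP2, LAMB1 and IL18 did not (0.0747 to 0.26). The number of genes past the threshold was 6 without library 2, 13 without library 3, 51 with DESeq2 and 0 with no library block, where 100 had an unadjusted p under 0.05.

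Subcluster 6 consisted of cells with few UMIs, with medians of 863, 720 and 1002.5 in libraries 1, 2 and 3 and 249, 113 and 94 cells. Their median mitochondrial share was 1.70%, 9.86% and 5.23%, against 7.18% to 9.34%, 7.60% to 12.3% and 9.92% to 13.2% in the other subclusters. CFD (2.68 ± 0.22), HLA-DPA1 (2.73 ± 0.45) and HLA-DRA (2.63 ± 0.41) were higher, and the adaptor SHC1 (-1.89 ± 0.48), SEL1L (-1.83 ± 0.40), FNIP2 (-1.76 ± 0.41), the kinase LATS2 (-1.69 ± 0.38), EZR (-0.61 ± 0.13), VIM (-0.48 ± 0.10), CFI (-0.89 ± 0.22) and IGFBP2 (-0.89 ± 0.21) lower, in 3 of 3 libraries (edgeR adjusted p from 6.34e-08 to 0.0485). Of the 3 higher genes, CFD was among the leading genes of fibroblast-like clusters, and HLA-DPA1 and HLA-DRA of myeloid-like clusters. FABP4 was called higher (5.64 ± 1.09, edgeR adjusted p = 0.00863) but in 1 of 3 libraries, and without library 2 its log2 difference was -6.33 (adjusted p = 1). Of 84 calls 23 were higher and 61 lower (27.4% higher), whereas with RLE size factors 28 were higher and 9 lower (75.7%), and SHC1, SEL1L, FNIP2, LATS2, EZR, VIM, CFI and IGFBP2 were not among them (edgeR adjusted p from 0.0672 to 0.221). Without library 1, 21 genes passed, without library 2, 24, and without library 3, 13. CFD passed in all 3 fits, and the 8 lower named genes failed in each of them, except SEL1L without library 1 (edgeR adjusted p from 0.0886 to 0.572 where they failed). HLA-DPA1 and HLA-DRA did not pass without library 2 (0.168 and 0.167). With doublets kept, 10 of the 12 named genes did not pass, CFI and IGFBP2 excepted (edgeR adjusted p from 0.161 to 0.998). With no library block 16 genes passed.

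Subcluster 7, with 28, 298 and 73 cells, was defined by haemoglobin transcripts (HBB, HBA1, HBA2), which were among the clustering genes. Of 5 genes past the threshold, ANGPTL7 (1.20 ± 0.24) and HHIP (1.06 ± 0.18) met the rule for named genes, both higher in 3 of 3 libraries (edgeR adjusted p = 0.0434 and 0.00848). In edgeR 437 genes had an unadjusted p under 0.05, DESeq2 called 11 and 2 passed with no library block. ANGPTL7 did not pass without library 1, 2 or 3 (adjusted p = 0.226, 0.487 and 0.0627), nor HHIP without library 3 (0.136). The other 3 genes were chosen after their values were seen: the globins HBD and HBM and the haemoglobin chaperone AHSP, with log2 ratios of CPM + 1 of 5.995, 4.33 and 3.06, of 4.27, 3.94 and 4.09, and of 4.49, 3.1 and 1.63 in libraries 1, 2 and 3. Their levels in the other subclusters lay near 0, at 0.0403, 0.0532 and 1.09 CPM, so no fitted fold is given.

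Levels in mesothelial-like cells also differed between the 3 libraries, without a group to explain it and without a test. Of the identity genes, SLPI stood at 1817, 1737 and 1602 CPM and MSLN at 735, 637 and 757 in libraries 1, 2 and 3, while KRT18 stood at 13703, 4555 and 1552 and ITLN1 at 4528, 15568 and 3079. Chemokines and stress genes also varied. CCL2, a monocyte attractant, stood at 2516, 1037 and 108 CPM, and IL6 at 292, 23.2 and 1.95. The metallothionein MT2A stood at 13765, 8012 and 1456 CPM and TXNIP, an inhibitor of thioredoxin, at 54.0, 1198 and 2437. HAS1 stood at 1340, 452 and 147 CPM, IER3 at 1219, 102 and 215, and the heat shock gene HSPA1B at 330, 1210 and 91.0. Over the members with at least 100 CPM, the median ratio of the highest to the lowest library was 23.2 for 3 chemokines and cytokines (1.57 to 149), 9.77 for 8 metallothionein and oxidative genes (1.13 to 45.1) and 9.10 for 3 hyaluronan and fluid genes (6.54 to 10.4). It was 5.004 for 16 immediate early and heat shock genes (1.29 to 13.3), 1.57 for 9 complement genes (1.23 to 5.65) and 1.75 for 3 junction genes (1.52 to 1.80).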

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

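The tests weighed in this part were chosen after the results were seen. Several cell types lay outside every comparison because they formed no named cluster of their own in every library. They are listed because each stood above the share that a count of 0 allows, which any cluster found would do, so this is no test. Mast-like cells, which carried the tryptases TPSAB1 and TPSB2, made up 0.781% of library 1 (27 of 3459 cells, against 0.0867% for a count of 0) and 0.245% of library 3 (32 of 13067, against 0.0230%). B-like cells, with MS4A1 and CD79A, made up 3.60% of library 2 (735 of 20434, against 0.0147%), and plasma-like cells, with JCHAIN and MZB1, 0.2398% (49 cells). An unnamed cluster of 15 cells in library 1 (0.434%) had a median of 739 UMIs and was led by CCL21, PPBP, FABP4, PF4, TFF3 and CLDN5, a mixture of lymphatic, platelet and endothelial genes. A library without such a cluster is not shown to lack the cells: in library 1, 9 of the 146 myeloid-like cells (6.16%) held at least 2 B cell markers. No biological explanation was tested.

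Mesothelial marker RNA in the T_NK-like cells of library 2 stood at 26.6% of the mesothelial-like level. Doublets would leave it in a minority of cells, but the median T_NK-like cell of library 2 held 15.8% of the mesothelial-like level, which argues against doublets as the only source. The 10% of these cells with the most marker UMIs held 55.1% of them, so doublets as part of the source stay open. Free mesothelial RNA would give every droplet about the same number of marker UMIs. The class medians of library 2 were 6 UMIs in T_NK-like, 6 in B-like, 5 in myeloid-like and 12 in fibroblast-like cells, and the highest was 2.4 times the lowest. T_NK-like, B-like and myeloid-like cells lay close together and fibroblast-like cells did not. Not every marker is low in fibroblast-like cells: in library 2, PRG4 stood at 867 CPM there, against 489 in mesothelial-like cells. The higher fibroblast-like median is thus no evidence against free RNA in the droplets, which stays open. No biological explanation was tested.

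Haemoglobin RNA defined subcluster 7. Red-cell genes that were held out of the clustering and lay under 5 CPM in the other subclusters were HBD, HBM and AHSP, and 100% of these 3 were higher in subcluster 7. All 3 had been seen as called before the list of red-cell genes was written, so this test decides nothing. RNA or cells of the red cell lineage in the same droplets stays open, and no biological explanation was tested.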

How the results depend on the processing

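The alternatives that subtracted mesothelial RNA, left out subclusters 6 and 7 or left out cycling cells were chosen after the data were seen; the rest were planned. Named genes of the class comparisons kept direction and threshold in 1937 of 2120 values and lost the threshold in 183, with 0 reversed; list results did so in 276 of 312, with 14 weaker and 22 stronger. Named genes of subclusters kept both in 648 of 944, lost the threshold in 288 and reversed in 8. The comparison with endothelial-like cells was not made, since no cluster carried that name. Resolution 0.2 gave no match for subclusters 2 and 3 (Jaccard index 0.297 and 0.217, under 0.3), and keeping doublets none for subclusters 5 and 7 (0.0431 and 0.00616). The cause was not tested except where the alternative itself uses fewer libraries or genes.

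Calls by setting, in the order fibroblast, myeloid, T_NK where 3 are given: doublets kept 470, 1100 and 644 genes (1324, 2802 and 2790 in the planned fit), and 43, 13, 121 and 172 in subclusters 1, 2, 3 and 6; myeloid-like cells then made up 5.77%, and 7.003% with a mitochondrial limit of 10%, where fibroblast-like cells made up 16.9% (within 1 SD) and no cluster was named mast-like or plasma-like. With no replicate block, 804 genes passed against fibroblast-like cells and 0, 0, 0, 247, 16 and 2 in subclusters 2 to 7, and 5 lists against fibroblast-like cells. With only the 2 classes in the fit 2086 passed against fibroblast-like cells. RLE size factors gave 49 and 37 in subclusters 2 and 6. No filter on low counts gave 86, 293, 877, 184 and 36 in subclusters 1, 2, 3, 6 and 7, DESeq2 33, 51, 137 and 11 in subclusters 1, 2, 6 and 7, and resolution 0.2 36, 290, 614, 22 and 8 in subclusters 1, 4, 5, 6 and 7. With an estimated correlation 0, 0 and 0 lists passed.

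Leaving out 1 library gave 632 to 1116, 1169 to 2587 and 1404 to 2061 genes in the class comparisons; 0 to 1, 6 to 67, 59 to 377, 3 to 1314, 478 to 881, 13 to 24 and 5 to 6 in subclusters 1 to 7; and 3 to 4, 5 to 7 and 8 to 11 lists. Subcluster 4 fell to 3 genes without library 2.

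Reversed with doublets kept: APOE 0.065 and MMP2 0.34 in subcluster 2, SEL1L 0.062, FNIP2 0.26, LATS2 0.15 and FABP4 -0.071 in subcluster 6. Leaving out 1 library gave -1.91 to 0.78 for CXCL3 in subcluster 3 (0.78 without library 1) and -6.33 to 6.81 for FABP4 in subcluster 6 (-6.33 without library 2).

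Depth and the spread between libraries were not told apart as limits. Fibroblast-like cells of library 3 held 975615 UMIs, and on simulated data 10%, 7% and 5% of 2-fold changes were recovered in the class comparisons and 32% in subcluster 6.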

Other observations

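The tests in this part were chosen after the results were seen. Myeloid-like cells held 2 kinds of cluster in libraries 2 and 3. In library 2, a cluster of 629 cells held the complement gene C1QA at 3802 CPM, the scavenger receptors CD163 and MARCO at 791 and 696 CPM and the lectin FCN1 at 86.7 CPM; a cluster of 492 cells held C1QA at 367, FCN1 at 604, S100A8 at 3105 and LYZ at 4575 CPM. In library 3, a cluster of 339 cells held C1QA at 4998, MARCO at 1280 and FCN1 at 85.3 CPM, and a cluster of 272 cells held C1QA at 792, MARCO at 19.6 and FCN1 at 575 CPM. Library 1 had 1 myeloid-like cluster of 146 cells, with C1QA at 1076 and FCN1 at 456 CPM. These genes are markers used in the clustering and are given as identity, without a test.

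Subcluster 5 held mesothelial genes, most of them at lower levels, beside its mesenchymal ones. The keratin KRT18 stood at 5251, 3097 and 1764 CPM in libraries 1, 2 and 3, against 13813, 4561 and 1544 in the other mesothelial-like cells. Mesothelin (MSLN) stood at 132, 252 and 257 against 743, 638 and 777, ITLN1 at 92.4, 3458 and 264 against 4586, 15619 and 3192, and UPK3B at 166, 305 and 292 against 681, 563 and 545. CDH1 (log2 difference -2.69 ± 0.69) and MUC16 (-1.63 ± 0.22) were called lower (edgeR adjusted p = 0.00809 and 7.62e-06, 3 of 3 libraries each). The collagen COL1A1 stood at 911, 440 and 582 CPM against 128, 122 and 155 in the other mesothelial-like and 964, 897 and 1166 in fibroblast-like cells. COL3A1 stood at 685, 620 and 681 against 39.6, 130 and 207, and 757, 1484 and 1555 in fibroblast-like cells, and PDGFRA at 156, 88.4 and 151 against 15.2, 13.9 and 18.2, and 126, 284 and 292. In library 1 these 3 lay near or above the fibroblast-like level. EGFL6 stood at 370, 139 and 290 CPM, against 0.755, 2.78 and 9.22 in fibroblast-like cells. The fibroblast genes PI16 (0, 0 and 0 CPM against 632, 351 and 498 in fibroblast-like cells) and APOD (7.34, 3.76 and 10.1 against 904, 562 and 4227) stood far below the fibroblast-like level.

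A candidate explanation for the mesenchymal genes of subcluster 5 is fibroblast-like cells or their RNA among its cells. The share of fibroblast-like RNA read from the markers was 7.04%, 2.65% and 7.14%, and it accounted for at most 17.1% of the excess of the median list member in any library, although for 3, 2 and 2 of the 10 members it reached 50% or more. Myeloid-like RNA accounted for at most 0.0210%, and without cycling cells 10 members were higher, the same 10 as with them. These tests argue against those 3 sources for the list as a set, but only for RNA with the average profile of the fibroblast-like or myeloid-like class. The fibroblast markers differed: in library 1, PI16 stood at 0 CPM and COL1A1 at 911 against 964 in fibroblast-like cells. Stromal cells with another profile, and doublets with them, were not tested. A mesothelial state with mesenchymal genes may remain as a hypothesis, which the labels give no group to test, and no biological explanation was tested.

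Other splits of the same sums asked whether chance could give as many calls. For the 3 class comparisons, 3 sums against 3 make 10 splits, too few for a share under 0.05. Only 4 of these splits put the 2 sums of every library on opposite sides, so the others ignore the pairing within libraries. The real split called 2086, 2966 and 2148 genes in a fit of the 2 classes, the highest other split 0, and 1 split, the real one, was as large in each. For the subclusters, 41 choices of 1 subcluster per library were compared, the real one included, in a fit of the chosen sums against all others, which calls other numbers of genes than the fit of all 7 subclusters. The highest of the other choices called 569 genes. For subcluster 5 (832 genes) 1 of the 41 choices was as large, and for subcluster 4 (466 genes) 2 were. The subclusters were formed by clustering these same cells of the 3 libraries together, and held-out genes can vary with the clustering genes. A choice matched over the libraries can thus call more genes than a mixed one by construction. These shares therefore cannot test chance, and 7 subclusters were tried besides, so neither excludes it. The calls of subcluster 4 fell to 3 without library 2 and to 0 with no library block in the fit of all 7 subclusters. Chance could not be excluded for subclusters 1, 2, 3, 6 and 7 either, where the real choice called 0, 1, 0, 59 and 3 genes and 41, 10, 41, 6 and 8 choices called as many. The choice with 569 calls, several times these counts, points to a structure among the sums: it joined subcluster 5 of libraries 1 and 3 with subcluster 4 of library 2. The next highest, with 173, 93, 79 and 64 calls, also held subcluster 4 of library 2. The choices therefore mix subclusters that differ, which limits what their counts say about chance.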
